A study of Mus musculus with 9 samples.

How the data were processed

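The series holds 9 samples, each a plate of single cells from mouse blastocysts. Per the labels' protocols, green cells were picked by hand into lysis buffer, reverse transcribed with template switching, and amplified in separate tubes with barcoded primers. Up to 96 barcodes were then pooled, amplified again with an index primer, and sequenced from the 3′ end of the mRNA. Reads were mapped with STAR to GRCm38, per the submitters' processing notes. The version of STAR, the gene annotation, the counting tool, the use of strand and of molecular identifiers are not given in the sources used here, so counting error is a lower bound on the error of a single value.

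The deposited values are whole-number counts per gene and cell, not normalized, in 2 tables of the whole series. The larger holds 579 cells and 21125 genes. The smaller holds 525 of these cells and 18280 of these genes, with 0 of the shared values differing, and its missing genes were each detected in at most 2 cells. The larger table was used throughout and the smaller as an alternative. Of the gene names in the larger table, 23 had been turned into dates, as a spreadsheet does, and were kept as they stand. Cells were assigned to plates by the plate, prefix and number in their column names. Among the columns, 36 of the larger table and 35 of the smaller carry the plate number 9 with the prefix mbs4, which matches no sample title, and were not used. Cells with the number 13 on plates 4 (8 cells) and 6 (5 cells) lie outside their titles' ranges. They were counted with their plates but left out of the tests between embryo numbers. No 2 cells had identical counts (0 repeated columns).

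The tests, gene lists, markers and alternatives were fixed before the data were examined, except where the text says otherwise. Cells with at least 2000 detected genes were kept. Counts were scaled to the median total and log-transformed, and the 2000 most variable genes, leaving out every gene of the 26 fixed lists, were reduced to 20 principal components with scanpy 1.11.5. A graph of 15 neighbours was clustered with the Leiden method (leidenalg 0.10.2) at resolution 0.5. Clusters were named from 4 marker lists (TE, epiblast, primitive endoderm, cumulus cells) by their mean standardised expression. The best list needed a mean above 0 and at least 3 markers above 0.2, and between TE and the ICM lists it had to lead by over 0.2. No lead over the cumulus list was required. A cluster also stayed unnamed if markers of another class outnumbered its own among its 10 leading genes, or if it was shallow for its plates and had none of its own there. The lead replaced a first rule, a mean above 0.2, after the clusters were seen, because the first rule left cluster 1 unnamed. Epiblast and primitive endoderm were pooled as ICM-like. No doublet caller was run, since cells had been picked one by one.

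The plate was the replicate. Shares of TE-like cells were compared by an exact two-sided permutation of plates. Scatter between embryo numbers was compared with 100000 permutations of classes within plates. For genes, counts were summed per plate, or per plate and class, and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Plates entered the TE-like test with at least 10 TE-like cells and the ICM-like test with at least 5 ICM-like cells. TE-like and ICM-like cells were compared with plate as a block on the 7 plates that met both minimums, over genes not used for clustering. SE values were obtained from the fold change and the F statistic. Gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated one. CPM values in the text are summed counts of a plate or class, scaled to a common library total.

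The alternatives were a minimum of 1000 or 4000 detected genes, the smaller table, resolution 1, 1000 variable genes, classes by marker score, embryo number as the replicate, embryos with at least 6 classed cells, DESeq2 size factors, no filter beyond 1 count, DESeq2 1.42.0, limma on log2(CPM + 1), cells thinned to 10000 counts, no plate block, and each plate left out. The edgeR step was tested on simulated counts with 200 changed genes, all drawn from genes above the median abundance. Of genes changed 4-fold it recovered 88% in TE-like cells (10187 genes), 79% in ICM-like cells (10032 genes), 98% over all cells (11951 genes) and 98% between classes (11332 genes). Of genes changed 2-fold it recovered 18%, 12%, 50% and 69%. Among unchanged genes it made 5, 5, 11 and 6 false calls.

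The named genes follow 1 rule, fixed beforehand. They are the called genes of the lists, up to 12 by smallest p, the 10 largest changes in each direction among called genes with a mean log2 CPM of at least 4 that are not Gm or Rik models, all called genes where fewer than 10 were called, and 10 regulators in every comparison. Called regulators beyond the 12 and examples within a list were added after their values were seen. Coordinates were taken from GENCODE vM21 on GRCm38, the build in the submitters' processing notes. Intervals of shares are exact binomial (Clopper-Pearson) at 95% and cover counting error only.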

Results

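Single cells of mouse blastocysts were profiled by sequencing the 3′ ends of their mRNA. The embryos carried the mTmG reporter, which switches a cell and its descendants to green fluorescence after Cre recombination. Cre mRNA had been injected into 1 blastomere at the 4- or 8-cell stage, and single green cells were picked by mouth pipette at the blastocyst stage. The samples are 9 plates of such cells, with the prefix mbs4 on 6 plates (plates 1 to 6) and mbs8 on 3 plates (plates 7 to 9). The labels do not say what the prefixes mean. Their digits match the 2 injection stages of the design, and the text keeps the prefixes as they stand. A number in each cell's name is treated below as an embryo number. It falls within the range in its plate's title except for number 13 on plates 4 and 6.

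Of 543 cells assigned to the 9 plates, 509 had at least 2000 detected genes and were kept. The total count per plate was 3125958, 2601235, 6449927, 3277245, 5584450 and 5101227 on plates 1 to 6, and 1832719, 7355653 and 2164108 on plates 7 to 9. A kept cell held a median of 36230 counts, with a range from 3288 to 663114, and a median of 5660 detected genes. The row for eGFP, the product of the recombined reporter, had at least 1 count in 393 of the 509 kept cells (77.2%, 95% exact binomial interval 73.3% to 80.8%). The share was 82.7% of ICM-like cells at a median of 47092 counts per cell and 73.0% of TE-like cells at 52925. No cells outside the green population were available as a background for this value. Per plate, eGFP stood at 399 ± 189 CPM (counts scaled to a common library total; SD, n = 6) under mbs4 and 275 ± 207 (n = 3) under mbs8. Nothing in the labels says that plates of 1 prefix came from separate experiments, so the p-values below measure the spread between plates, which may be technical.

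Clustering of the cells gave 6 clusters, of which 4 could be named from markers fixed beforehand. Clusters 2 and 3, with 108 and 55 cells, carried markers of the trophectoderm, the outer epithelium of the blastocyst that founds the placental trophoblast, and are called TE-like. Clusters 1 and 4, with 146 and 50 cells, carried markers of the inner cell mass (ICM), and are called ICM-like. Markers of epiblast and of primitive endoderm, the 2 lineages that arise from the ICM, were raised together in both of these clusters, so neither lineage was separated and the share of primitive endoderm among ICM-like cells was not computed. Cluster 0, with 120 cells at a median of 16930 counts, and cluster 5, with 30 cells that all came from plate 6, stayed unnamed. The unnamed share of kept cells was 36.3% ± 13.8 (SD, n = 6) on mbs4 plates and 11.2% ± 16.2 (n = 3) on mbs8 plates. The naming rule was changed after the data were examined, and the change is what named cluster 1, whose epiblast marker mean was 0.147 against 0.0476 for cumulus markers. The ICM-like class on plates 1 to 7 rests on it, since the other ICM-like cluster held 3 cells of mbs4 plates and 47 of mbs8 plates. Of the cells of clusters 3 and 4, 89.1% and 94.0% came from plates 8 and 9. Clusters 1 and 2 held nearly all classed cells of plates 1 to 7, with plate 7, an mbs8 plate, among them.

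The design asks whether the progeny of 1 blastomere is biased towards TE or ICM. TE-like cells made up 42.4% ± 10.7 (SD, n = 6) of the classed cells on mbs4 plates and 46.4% ± 11.7 (SD, n = 3) on mbs8 plates. The difference of 3.98 percentage points was smaller than the spread between plates (two-sided exact permutation test over 84 splits of the plates, p = 0.607). Shares per plate ran from 23.3% of 43 cells on plate 3 (95% exact binomial interval 11.8% to 38.6%) to 55.8% of 77 cells on plate 8 (44.1% to 67.2%). The sign of the difference depended on how cells were classed. It was -11.3 and -19.8 points with at least 1000 and 4000 detected genes per cell. In the smaller table it was -7.48, at resolution 1 -2.29 and by marker score -2.97 points. With 1000 variable genes it was 9.64 points. The smallest p of these was 0.0595, with at least 4000 detected genes (exact permutation test). Unnamed cells, a mean of 36.3% of kept cells on mbs4 plates and 11.2% on mbs8 plates, lie outside these shares.

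**Figure D1:**
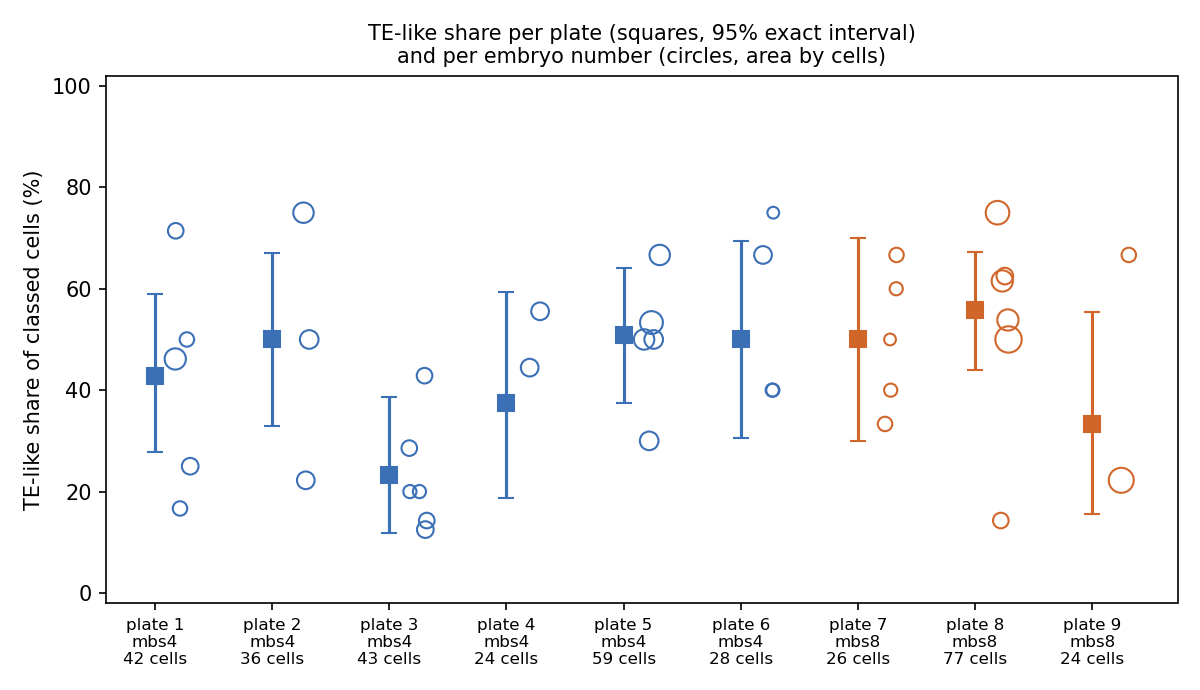
TE-like share of the classed cells, in percent, for each plate (squares, with 95% exact binomial intervals) and for each embryo number with at least 3 classed cells (circles, with area proportional to the number of cells). Plate shares lie between 23.3% and 55.8%, the 2 prefixes overlap, and no embryo number lies at 0 or 100%.

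Each of the 38 embryo numbers with at least 3 classed cells held both TE-like and ICM-like cells. There were 25 such embryos with 210 classed cells under mbs4 and 13 with 127 cells under mbs8. If the progeny of each labelled blastomere had leaned to 1 class, embryo shares would have scattered more widely than cells permuted within their plate. Under mbs4 the observed scatter was 0.998 times the permuted mean (one-sided permutation test, 100000 permutations, p = 0.465). Under mbs8 it was 1.29 times (permutation p = 0.224). In simulations of the same embryos and cell numbers, true embryo shares of either 25% or 75% were detected in 100% of 200 runs under mbs4 and in 94.5% under mbs8. Shares of 35% or 65% were detected in 64.5% and 50% of runs, so a lean of that size was not excluded. The runs held no errors of classing and no unnamed cells, so they may overstate what the data could detect. In 2 other ways of classing cells the scatter passed 0.05 under 1 prefix, at 1.46 times (permutation p = 0.0473) for mbs4 in the smaller deposited table and 1.94 times (permutation p = 0.0348) for mbs8 with 1000 variable genes.

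The series set out to look at regulators of the choice between TE and ICM, and some of these differed between the classes within the same plates. Cdx2 and Gata3, transcription factors of the trophectoderm, stood at 198 ± 74.1 and 825 ± 188 CPM (SD, n = 7 plates) in TE-like cells against 28.9 ± 12.9 and 107 ± 95.03 in ICM-like cells. Their log2 fold changes were 2.77 ± 0.24 and 3.34 ± 0.36 (SE; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.2e-06 and 2.2e-05). Sox2, a pluripotency factor, went the other way, at 14.5 ± 17.2 CPM in TE-like and 229 ± 125 in ICM-like cells (log2 fold change -4.17 ± 0.37). Cdx2, Gata3 and Sox2 were among the markers used to name the clusters, although no gene of the fixed lists was used to form them, so their differences are partly built in. All 3 differed in the same direction on 7 of 7 plates.

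Of 49 measured regulators on 4 fixed lists, 11 were higher and 5 lower in TE-like cells over all 10710 genes held out of clustering, and 16 and 12 adjusted over the list alone. Among the 41 that were not naming markers, 9 were higher and 3 lower. Tead4, the DNA-binding partner of the Hippo effector Yap1, was higher in TE-like cells (193 ± 23.0 against 70.5 ± 16.9 CPM, n = 7, log2 fold change 1.49 ± 0.17). Tfap2a (log2 fold change 3.41), Id2 (3.19), Gata2 (2.97), Grhl2 (1.10), Klf5 (0.87) and Klf6 (0.83) also rose, as did the DNA methyltransferase Dnmt3b (218 ± 67.4 against 94.9 ± 26.6 CPM) and its cofactor Dnmt3l (log2 fold change 1.10). Esrrb, an orphan nuclear receptor of both pluripotent and trophoblast stem cells, was lower in TE-like cells (19.8 ± 14.1 against 112 ± 36.1 CPM). Etv5 (log2 fold change -2.47), Hand1 (-1.95) and Gata6 (-0.50), a primitive endoderm factor and naming marker, were lower too.

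Other regulators were not called over all genes. Carm1, an arginine methyltransferase, and Sox21, both studied for differences between blastomeres of the 4-cell embryo, had log2 fold changes of -0.04 ± 0.23 (57.3 ± 21.8 against 57.1 ± 11.8 CPM) and -1.10 ± 0.43 (14.5 ± 8.80 against 28.4 ± 14.99 CPM; adjusted p = 0.960 and 0.192 by edgeR). Sox21 was lower in TE-like cells on 7 of 7 plates. Nanog, another pluripotency factor, stood at 433 ± 129 CPM in TE-like and 478 ± 164 in ICM-like cells (adjusted p = 0.851 by edgeR). Eomes (0.83), Tfap2c (0.50) and Pou5f1 (-0.53) were not called over all genes either. Adjusted over the 49 regulators alone, Sox21, Eomes and Tfap2c passed (unadjusted p = 0.0213, 0.0172 and 0.0129 by edgeR). Nanog, Pou5f1 and Carm1 did not pass there. Cdx2 lies on chromosome 5 (147300805 to 147307270), Gata3 on chromosome 2 (9857078 to 9890034), Tead4 on chromosome 6 (128224288 to 128300823), Sox2 on chromosome 3 (34650405 to 34652461), Nanog on chromosome 6 (122707489 to 122714633), Carm1 on chromosome 9 (21546894 to 21592623) and Sox21 on chromosome 14 (118233232 to 118237030) of GRCm38. Each is annotated as a protein-coding gene in GENCODE vM21.

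**Figure D2:**
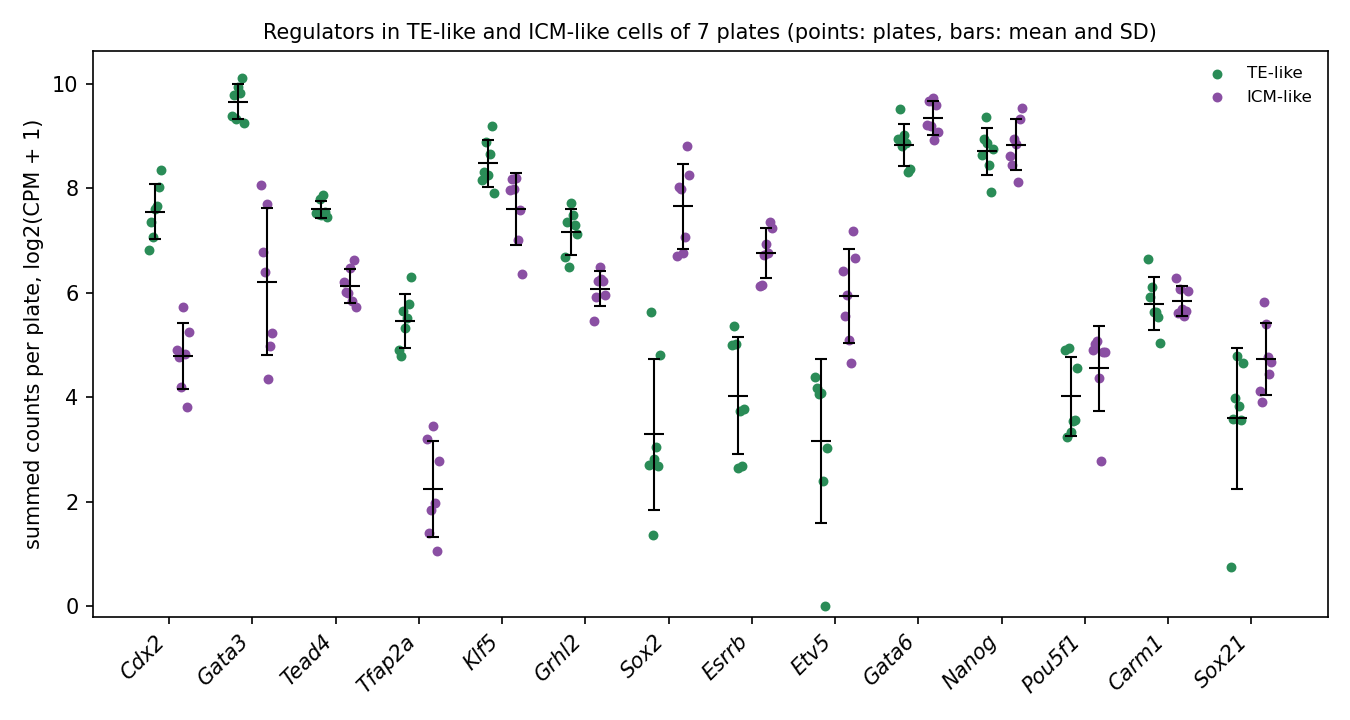
Summed counts per plate, as log2(CPM + 1), for 14 regulators in TE-like (green) and ICM-like (purple) cells of the 7 plates that held enough of both. Points are plates, and bars give the mean and SD over 7 plates. Cdx2, Gata3, Tead4, Tfap2a, Klf5 and Grhl2 lie higher in TE-like cells, and Sox2, Esrrb, Etv5 and Gata6 higher in ICM-like cells. The 4 on the right were not called over all held-out genes, though Sox21 passed adjusted over the regulators alone.

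Over all held-out genes, 355 were higher and 197 lower in TE-like cells. Epithelial genes were among those that rose. Of 26 measured genes of cell polarity and junctions, 12 were higher and 1 lower (15 and 2 adjusted over the list alone), with Tjp2, a tight junction scaffold (339 ± 140 against 127 ± 34.6 CPM), the desmosomal cadherin Dsg2 (log2 fold change 1.64) and Cldn4 (1.92), a claudin and naming marker, among those that rose. Ezr, which links actin to the membrane, was the member that fell (log2 fold change -1.59). Of 11 genes of blastocoel formation, 5 rose and 0 fell, among them Atp1b1 (1.29), a sodium pump subunit, and Aqp3 (0.69), a water channel, both naming markers. Of 13 measured mural TE genes 8 rose and 1 fell, with the keratins Krt8 (637 ± 136 against 154 ± 76.7 CPM) and Krt18 (936 ± 269 against 167 ± 143), again naming markers, Ndrg1 (2.24) and Basp1 (1.11). These lists and the TE regulators, with 9 of 19 higher and 2 lower, were called by camera with a preset correlation of 0.01, and the 4 kept their calls with an estimated correlation (adjusted p from 0.00703 to 0.0356). These calls are partly built in, since the lists hold naming markers. Without those markers, a setting chosen after seeing the data, TE regulators, mural TE and polarity and junctions passed with an estimated correlation (adjusted p = 0.0254, 0.0254 and 0.0130), and blastocoel formation did not (0.194).

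Signalling and metabolic lists were mixed. Hk2, the hexokinase at the entry to glycolysis, rose from 76.6 ± 24.5 to 288 ± 74.3 CPM in TE-like cells, but 2 of 15 glycolysis genes were called. Among BMP genes 3 rose and 2 fell, with Id3 (-2.58) and the receptor-like Bambi (-2.43) lower. Among FGF and ERK genes 4 fell, including Fgf4 (-2.52) and Spry2 (-0.98), and Frs2 rose (0.98). Camera also called primitive endoderm regulators, p53 and apoptosis genes, imprinted genes and 2-cell-like transcripts as lower in TE-like cells with the preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.222, 0.242, 0.167 and 0.222). For the 2-cell-like list, transcripts of the embryonic genome's first activation, 4 of 5 measured members were lower, but their level came from few cells. Usp17la had a log2 fold change of -5.76 with all cells and of -1.11 (adjusted p = 0.756 by edgeR) without the 2 cells that held at least 0.5% of their counts on this list. That alternative was chosen after seeing the data. Usp17la and Usp17lc belong to a family of near-identical copies, so their counts are uncertain.

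The remaining genes with the largest changes were Trpm6 (log2 fold change 4.18), a magnesium channel, Wnt3a (3.89), Tmem125 (3.84), Frk (3.25), Hs3st3b1 (3.17), the naming marker Dppa1 (3.16) and Tcf15 (3.02) among those higher in TE-like cells. Those lower were Usp17la, Usp17lc (-5.71), Zfp352 (-5.30), Pdgfra (-5.28), a receptor of the primitive endoderm and a naming marker, Nkx6-2 (-3.54), Lbx1 (-3.49), Tbx15 (-3.31), the imprinted noncoding RNA Meg3 (-2.83) and Fam25c (-2.76). Ddah1, a polar TE gene, also rose (1.30). Since classes were formed from the same cells, these p-values describe how far the classes differ and not whether 2 classes exist. Leaving out plate 8 moved the number of called held-out genes from 552 to 300, of which 296 were shared with all plates.

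Between the prefixes, edgeR called few genes within a class in the main setting. In TE-like cells of plates 1, 2, 3, 5 and 6 against plates 7 and 8, 2 of 10686 genes were higher and 3 lower under mbs8. Cdkn1a, the cell cycle inhibitor induced by p53, was at 49.9 ± 11.9 CPM (SD, n = 2) under mbs8 and 181 ± 36.6 (n = 5) under mbs4 (log2 fold change -1.87 ± 0.32, adjusted p = 0.0368 by edgeR). Ift74, a ciliary transport protein, was also lower (15.2 ± 6.17 against 97.5 ± 14.4 CPM). H2-Ab1, a class II histocompatibility gene, was at 0.155 ± 0.220 against 30.1 ± 13.1 CPM. Wipf1, an actin regulator, was higher (359 ± 95.2 against 112 ± 15.5 CPM), as was Gulp1, an engulfment adaptor (88.7 ± 76.2 against 8.23 ± 2.46). Each of the 5 differed in the same direction on both mbs8 plates against every mbs4 plate, but 0 were called without plate 1 or without plate 3 (852 and 962 genes at an unadjusted p under 0.05, edgeR). DESeq2 called 54 genes, and edgeR with sums per embryo number called 222 of 7232. That last fit had no term for plate and counted embryos of 1 plate as separate replicates, so its calls may be too many. Most TE-like cells of plate 8 fell in cluster 3 and those of the other plates in cluster 2.

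None of the regulators was called over all genes between prefixes in TE-like cells. Adjusted over the list alone, 2 TE regulators were higher, and 1 pluripotency and 2 primitive endoderm regulators lower. Cdx2 was at 292 ± 48.3 CPM (n = 2, range 258 to 326) under mbs8 and 160 ± 37.6 (n = 5, range 112 to 200) under mbs4, with a log2 fold change of 0.83 ± 0.26 (adjusted p = 0.302 by edgeR). Log2 fold changes were 1.07 for Eomes, 0.02 for Gata3, 0.26 for Tfap2c, -0.52 for Nanog, -0.76 for Gata6, -0.84 for Carm1, -0.05 for Pou5f1, 0.36 for Sox2 and 0.39 for Sox21, none of them called over all genes. Cdx2 was among the TE regulators, and Gata6 among the primitive endoderm regulators, that passed adjusted over their list alone. On the fixed lists, camera with the preset correlation called 9 of 23 in TE-like cells. Polarity and junctions, blastocoel formation, glycolysis and S phase were higher under mbs8, with medians of log2 fold change of 0.24, 0.25, 0.45 and 0.21. Ribosomal proteins (-0.24), G2 and M phase (-0.26), p53 and apoptosis (-0.43), immediate early genes (-0.51) and mitochondrially encoded genes (-0.55) were lower. No list kept its call with an estimated correlation (smallest adjusted p = 0.193), and Cdkn1a was the only called member of any of them. With sums per embryo number, where embryos of 1 plate counted as separate replicates, 1 list passed with an estimated correlation. In TE-like cells 88% of genes changed 4-fold and 18% of those changed 2-fold were recovered in simulated counts. The changed genes all lay above the median abundance, so recovery of lower genes is not known. With 200 genes changed at once the adjustment is less strict than with few, so recovery may be lower where few genes change.

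In ICM-like cells, from all 9 plates, 2 of 10445 genes were higher and 3 lower under mbs8. Nedd4, a ubiquitin ligase, was at 267 ± 73.7 CPM (n = 3) against 79.6 ± 10.8 (n = 6), with a log2 fold change of 1.71 ± 0.24 (adjusted p = 0.0411 by edgeR). Ren1, the renin gene, was at 44.1 ± 33.5 against 0.794 ± 1.198 CPM. Dhdh, a dihydrodiol dehydrogenase (120 ± 11.7 against 553 ± 222 CPM), Slc35e4 (12.1 ± 3.69 against 72.7 ± 24.5) and the antisense gene Gm11961 (68.2 ± 21.0 against 366 ± 135), whose counts cannot be told from its sense partner's without strand, were lower. All 5 separated the 3 mbs8 plates from the 6 mbs4 plates. Gata3 (-2.10 ± 0.58), Sox2 (0.93), Sox21 (0.71), Tfap2c (0.63), Pou5f1 (0.60), Nanog (0.59), Eomes (0.49), Gata6 (-0.21), Cdx2 (0.15) and Carm1 (0.03) were not called over all genes. Adjusted over their list alone, Gata3 passed among the TE regulators, and Sox2 and Nanog among the pluripotency regulators. Without plate 1, 2, 5, 8 or 9 the count fell to 0 (1323, 1453, 1350, 1352 and 1121 genes at an unadjusted p under 0.05, edgeR). DESeq2 called 326. ICM-like cells of plates 8 and 9 lay mostly in cluster 4 and those of plates 1 to 7 in cluster 1.

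Over all kept cells, with no class call, 19 of 12307 genes were higher and 23 lower under mbs8. Spp1, which encodes osteopontin, was at 109 ± 86.6 CPM (n = 3) against 9.52 ± 5.17 (n = 6), with a log2 fold change of 3.52 ± 0.50 (adjusted p = 0.0116 by edgeR). The transcription factor Tbx15 (78.3 ± 24.4 against 11.3 ± 8.57 CPM), Nedd4 (209 ± 76.3 against 72.4 ± 14.5) and the 5-methylcytosine dioxygenase Tet2 (445 ± 8.03 against 271 ± 23.2), the called member of the pluripotency list, were higher too. So were Chsy1 (log2 fold change 3.21), Gulp1 (2.62), Tat (2.06), Trim30a (1.62), Rfx2 (1.47), Tdgf1 (1.40), an epiblast naming marker, and Kif16b (1.40). Of 20 measured p53 and apoptosis genes, 2 fell and 0 rose (10 and 0 adjusted over the list alone). These were Cdkn1a (52.5 ± 21.6 against 308 ± 191 CPM, log2 fold change -2.57) and Ccng1, another p53 target (91.3 ± 34.7 against 214 ± 51.9). The other genes with the largest falls were Mbnl1 (-4.59), Aoc3 (-3.52), Efna3 (-2.90), Rtkn (-2.62), Ptp4a3 (-2.42), Lrrc8e (-2.18), Chrna9 (-2.17), Asap3 (-1.79) and Elf1 (-1.76).

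The 10 regulators given throughout were not called over all genes in all kept cells, with log2 fold changes from -0.39 for Gata3 to 0.90 for Eomes. Adjusted over the TE regulators alone, Eomes passed (unadjusted p = 0.0044 by edgeR). Cdkn1a lies on chromosome 17 (29090976 to 29100727), Spp1 on chromosome 5 (104435118 to 104441050), Tbx15 on chromosome 3 (99240381 to 99354259), Nedd4 on chromosome 9 (72662346 to 72749852) and Tet2 on chromosome 3 (133463679 to 133545139). The count depended on which mbs8 plates were included. Without plate 7 it was 62, with 27 of the 42 genes shared. Without plate 9 the count was 0 (1339 genes at an unadjusted p under 0.05, edgeR), without plate 8 it was 10, and with plate 7 as the lone mbs8 plate it was 1. That last setting was chosen after seeing the data.

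**Figure D3:**
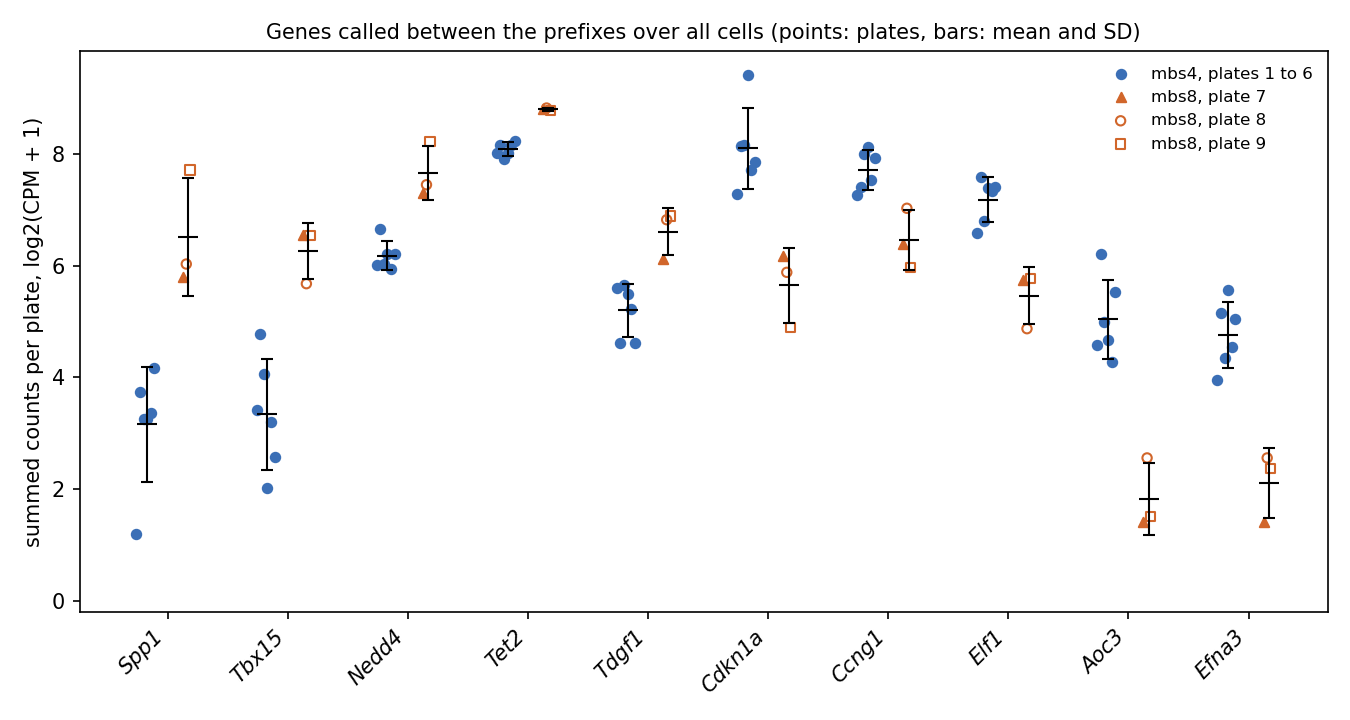
Summed counts of all kept cells per plate, as log2(CPM + 1), for 10 genes called between the prefixes. Points are plates, with separate symbols for plates 7, 8 and 9, and bars give the mean and SD over 6 mbs4 and 3 mbs8 plates. In these genes the 3 mbs8 plates lie outside the range of the 6 mbs4 plates.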

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

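The rules for single plates and for opposite contrasts were set beforehand, and the edgeR fit of class by prefix given for Nanog was not planned and was added after the data were examined. Among 111 sets of plates of the same kind, 11 had 1 plate far from the others by Dixon's ratio, where chance gives about 5.5. In TE-like over ICM-like log2 ratios, the plate furthest out was plate 8 for Carm1 (-0.998, ratio 0.642), plate 1 for Ddah1 (0.16, ratio 0.578), plate 7 for Etv5 (-7.19, ratio 0.574, with no Etv5 counts in its TE-like cells), and plate 3 for both Grhl2 (0.26, ratio 0.693) and Wnt3a (-0.86, ratio 0.684). Among mbs4 plates over all cells, Mbnl1 was highest on plate 6 (ratio 0.655), Nedd4 highest on plate 2 (ratio 0.631) and Spp1 lowest on plate 1 (ratio 0.694). Within a class, Gm11961 was lowest on plate 4 in ICM-like cells (ratio 0.634), Eomes lowest on plate 1 in TE-like cells (ratio 0.728) and Gulp1 lowest on plate 6 in TE-like cells (ratio 0.715).

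Nanog was the named gene whose contrast between classes had opposite signs under the 2 prefixes. Its log2 ratio of TE-like over ICM-like cells was above 0 on each of the 5 mbs4 plates tested, with a mean of 0.26. On mbs4 plates 1 and 5 it was barely above 0, at 395 against 391 CPM and 466 against 461 CPM. The ratio was below 0 on both mbs8 plates, with a mean of -1.09. The difference between the means was -1.34. In an edgeR fit with a term for class by prefix, the same difference was -1.34 ± 0.25 (SE), with an adjusted p of 0.244. That fit called 0 of 10710 genes, with 591 at an unadjusted p under 0.05. No explanation of it was tested.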

How the results depend on the processing

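The settings with lists without the naming markers, without plates 8 and 9, without or with number 13 and without the 2 cells rich in 2-cell-like transcripts were added after seeing the data, and the cause of each change below was not tested. No paired analysis between prefixes was run, because no plate used held cells of both prefixes. The columns with plate number 9 and prefix mbs4 were set aside. The share of primitive endoderm was not run. The difference of TE-like share never passed 0.05. It was -11.3 points with at least 1000 detected genes, -19.8 with 4000, -7.48 in the smaller table, -2.29 at resolution 1, -2.97 by marker score, and -0.743 to 10.5 with 1 plate left out. Embryo scatter passed 0.05 at 1.46 (mbs4, smaller table) and 1.94 (mbs8, 1000 variable genes), with ranges of 0.766 to 1.13 and 1.04 to 1.91 over plates left out.

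Genes called between prefixes varied most. In TE-like cells the 5 became 1 with at least 1000 or 4000 genes or at resolution 1, 0 in the smaller table or by marker score (953 and 1025 at an unadjusted p under 0.05, edgeR), 14 with 1000 variable genes (2 mbs4 plates and 1 mbs8 plate), 163 with no filter, 54 by DESeq2, 9 by limma, 222 with sums per embryo number, 8 with thinned cells, 20 without plates 8 and 9, and 0 to 20 over plates left out. In ICM-like cells the 5 became 25 and 14 with at least 1000 and 4000 genes, 34 at resolution 1, 10 by marker score, 40 with no filter, 326 by DESeq2, 61 by limma, 134 with sums per embryo number, 0 without plates 8 and 9 (713 at an unadjusted p under 0.05), and 0 to 48 over plates left out. Over all cells the 42 became 10 in the smaller table, 154 with no filter, 401 by DESeq2, 88 by limma, 295 with sums per embryo number, 1 without plates 8 and 9, and 0 to 84 over plates left out. Fits with 1 plate under mbs8, those with 1000 variable genes in TE-like cells among them, assume that it varies like the mbs4 plates. Fits with sums per embryo number had no term for plate and counted embryos of 1 plate as separate replicates, so their calls may be too many.

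Between classes, the 16 regulators became 25 with at least 1000 genes and at resolution 1 and 28 in the smaller table, with 11 to 18 over plates left out. The 552 held-out genes became 862, 1171 and 838 with at least 1000 genes, in the smaller table and at resolution 1, 358 with 1000 variable genes (3 plates in place of 7), 877 by DESeq2, 300 without plates 8 and 9, and 300 to 559 over plates left out. In settings with other clusters these counts may include genes used for clustering there. Called lists fell from 9 to 4 between prefixes and from 8 to 4 between classes with 1000 variable genes on these fewer plates, and from 4 to 0 with an estimated correlation. Over plates left out they ran from 4 to 9, from 6 to 10 and from 3 to 4. With at least 4000 genes the 2-cell-like genes Usp17la (3.20), Usp17lc (3.10) and Zfp352 (4.47) turned higher in TE-like cells. Over the 38 named genes called between classes, 693 of 746 values kept sign and call, 50 lost the call and 3 reversed. Between prefixes fewer values kept both, 256 of 415 over all cells, 55 of 104 in ICM-like and 42 of 96 in TE-like cells.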

Other observations

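The tests of plates 8 and 9, of the class mix, of crosstalk, of depth on plate 6, of gene length and of Y-linked counts, and the list tests in ICM-like and all cells, were chosen only after the results they bear on were seen. Beyond the comparisons above, camera with the preset correlation called 7 of 24 lists between prefixes over all cells and 2 of 24 in ICM-like cells, none of which passed with an estimated correlation. Over all cells these were p53 and apoptosis and ribosomal proteins, lower under mbs8, and pluripotency, polarity and junctions, glycolysis, BMP signalling and oxidative phosphorylation, higher. In ICM-like cells they were p53 and apoptosis, lower (adjusted p = 3.9e-04), and pluripotency, higher. The smallest adjusted p over all cells was that of p53 and apoptosis (median log2 fold change -1.03, adjusted p = 1.19e-06, and 0.414 with an estimated correlation). Members beside Cdkn1a and Ccng1 that did not pass edgeR's test had log2 fold changes of -1.65 for Phlda3, -1.59 for Bbc3, -1.09 for Trp53inp1, -1.04 for Mdm2 and 0.19 for Bax. In ICM-like cells the pluripotency list had higher values under mbs8 (median log2 fold change 0.59, adjusted p = 0.00184, and 0.113 with an estimated correlation). No member was called over all genes and 6 of 17 were higher adjusted over the list alone, with Klf2 at 1.46 and Tet2 at 0.88.

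Some levels stood out without a comparison. Pou5f1 was at 17.2 ± 9.61 CPM in TE-like and 25.0 ± 9.41 in ICM-like cells, against 478 ± 164 for Nanog and 660 ± 146 for Gata6 in ICM-like cells (SD, n = 7 plates). Cga, Pgf and Foxo6 had 83.7, 57.7 and 40.1 CPM on plate 1 and 124, 137 and 100 CPM on plate 2, with at most 5.32, 6.51 and 11.8 CPM on the other plates, and Cga had counts in 54 of the 62 kept cells of plate 1. Cyp19a1, Tfpi2, Pappa2, Adam12 and Ebi3, looked at beside them, did not go with them, with at most 0.776 CPM on plates 1 and 2. Gdf15, also looked at, had no counts on plate 1 and 6.98 CPM on plate 2, below the 10.997 CPM of plate 4. The columns of the smaller table stand in 2 runs of 321 and 204. The first held 152 TE-like, 13 ICM-like and 104 unnamed cells, and the second 1, 160 and 32.

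The genes called between prefixes over all cells could reflect the prefix or the plates. Of the 84 splits of the 9 plates into 6 and 3, 1 called as many genes as the real one. It was the real split, with 42 genes, and the highest other called 2, so chance assignment is argued against. The 6 splits that put plates 8 and 9 with an mbs4 plate called at most 1. A different mix of TE-like and ICM-like cells is argued against too, by the change of the called genes within a class. Its median was 106.2% of that over all cells in TE-like cells and 121% in ICM-like cells. Epiblast and primitive endoderm were not separated, and the epiblast marker mean was 0.605 in cluster 4 against 0.147 in cluster 1. A different mix inside the ICM-like class is therefore not covered. Over the 62 genes called with plates 8 and 9 alone as mbs8, plate 7 was shifted the same way in 50, by a median of 42.53% of the shift of plates 8 and 9. Plate 7 shifted by 0.639, outside the -0.0694 to 0.0971 of mbs4 plates left out in turn, though the genes were picked with those plates in the fit. With 1 such plate and an intermediate shift, these values do not tell a batch of plates 8 and 9 apart from the prefix, and the injection stage stays open as untested. The unused columns with plate number 9 and prefix mbs4 might bear on this and were not compared. For ICM-like cells, 1 of the 84 splits, the real one, called as many as 5 genes, with 4 for the highest other. For TE-like against ICM-like cells, 1 of 64 swaps of class within plates called as many as 552 held-out genes (highest other 4) and 1 of 64 as many as 16 regulators (highest other 0). Because the classes were formed from the same cells, swapped splits lose calls by construction, so these counts exclude nothing.

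Usp17lc and other 2-cell-like transcripts on plate 6 may come from 1 cell, which held 4181 counts of that list (0.879% of its total), with 1964 counts of Usp17lc against 213 spread over 55 of the 69 other cells of the plate and 22 over 392 cells of the plates without such a cell. Over 75 genes marking that cell, its plate mates held a median of 9.17% of its counts, with a fold of 2.032 between quartiles, where crosstalk between barcodes was taken to need under 2. Their level in CPM was 2.17 times the highest plate without such a cell, where 3 was needed, so crosstalk was not decided, and measures chosen knowing this gave a fold between quartiles of 8.21 for the 75 genes on plates without such a cell and, for list members alone, 13.2 times on plate 6 (6 members) and 1.41 times on plate 8 (4 members, another source cell). Deeper sequencing of plate 6 is argued against, since depth leaves CPM as it is and 4 of 14 list members, Zfp352, Usp17la, Usp17lb and Usp17lc, stood above every plate without such a cell (Usp17la 27.0 against at most 0.775 CPM, bootstrap 95% interval of the difference 18.05 to 37.73). Another member, Eif1a, lay below the highest of those plates (221 against 329 CPM, interval of the difference -178 to -38.9). This test followed 3 that decided nothing, by the 2.17, by the median total of a cell (56.0% of the deepest plate's, 33.1 to 178) and by the sum of the 14 members (0.957 times, 0.772 to 1.198), of which Eif1a made up 221 of 315 CPM, and crosstalk remains a hypothesis, with expression in the mates not tested.

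Unnamed cells gathered in some embryos. Over 47 embryo numbers their scatter was 4.05 times the permuted mean (permutation test, p = 1e-05, the smallest that 100000 permutations can give), with 1 embryo wholly unnamed and 13 with 0 unnamed cells. They were shallow, at a median of 18289 counts against 51070 for named cells. Both hold for the main setting, the only one tested for gathering. With 1000 variable genes 1 unnamed cluster was deep (147 cells, median 62712 counts), and with at least 4000 genes every cluster was named. Depth alone is argued against, since the ratio was 3.244 when cells were permuted within plate and depth class (3 per plate). Counts from introns or genomic DNA were expected to favour long genes, but rho between gene length and the change in cluster 0 was -0.02784 across 11334 genes, which are not independent replicates. The counting tool is not known, and counts limited to exons need not follow gene length, so this does not exclude such counts. Loss of RNA in whole embryos, or a difference in their stage, remains possible and was not tested.

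The number in the cell names may mark an embryo, as was assumed. Cells with a count on any of 4 Y-linked genes gathered by number, with 2.137 times the scatter of cells permuted within plates (permutation test, p = 0.00046). That argues against numbers unrelated to the cells. Depth was not held fixed here, and depth shared within a number could also gather such cells, so it does not show that numbers mark embryos.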
